A study of Homo sapiens with 2 samples.

How the data were processed

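RNA of 2 HES2 cultures was sequenced, with 1 library per group. HES2 is an established human embryonic stem cell line. Per the labels, one culture had received the empty PiggyBac (PB) transposon plasmid and the other the same plasmid carrying Tfcp2l1 (PB-Tfcp2l1). Both were grown for 3 passages in N2B27 medium with 10% KSR, to which activin A and FGF2 were each added at 10 ng/ml. RNA was extracted with Trizol, and libraries were sequenced on a BGISEQ-500.

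The authors deposited a single table of 18256 genes, 17579 with a symbol and 677 without. Per the submitters' processing notes, Bowtie 0.12.2 and the hg19 build were used. The annotation, the counting tool, any poly(A) selection of the RNA and the use of strand are not given in the sources used here, so genes that overlap, lie antisense to another gene or have near-identical copies are uncertain. The authors' expression columns are read here as FPKM (fragments scaled by gene length and sequencing depth). Per the file headers they hold only "expression", and the unit was inferred from the values, since expression times length added up to nearly the same total in both columns, as depth-scaled values do. The lowest deposited FPKM, 0.01, was taken to stand for 0, except in genes long enough that it amounts to 2 or more reads, where it was taken as measured. The deposited log2 ratio equals the log2 of the FPKM of PB-Tfcp2l1 over that of PB, with no other pseudocount. The deposited p-value of each gene compares the 2 libraries, and it behaved as a Poisson test on reads does. The authors' FDR column and their Up and Down calls were copied as deposited. Such a p-value compares these 2 libraries, not the conditions, because no spread between cultures enters it.

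Read counts were recovered from the deposited p-values. For genes listed at 0.01 in one library, the p-value falls by a constant factor with each read in the other, and it gave whole reads (within 0.02 of a read) for 485 of 556 genes in PB and 508 of 579 in PB-Tfcp2l1. With the FPKM of 36 and 29 of these genes, and with 65 bases taken off each length, the depth came to 23120000 reads in PB and 23140000 in PB-Tfcp2l1. Implied reads per gene follow from FPKM, length and depth. P-values recomputed from them lay on the same side of 0.001 as the deposited p-values for 96.3% of 18256 genes. At the median length of measured genes, 1 FPKM corresponds to 69.3 reads. Ratios are FPKM ratios of PB-Tfcp2l1 over PB. Their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals on implied reads, and they cover counting error only.

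The planned design assumed counts per gene, with a ratio of at least 2 among genes of at least 50 reads in the higher library. The table held FPKM, so the planned fallback was used, with differences of log2(FPKM + 1) among genes of at least 1 FPKM in the higher library, called measured genes. A gene was called higher or lower at a difference of at least 2-fold on that scale, which understates the ratio of genes with low FPKM. With 1 library per group no test was run, and no p-value was computed across genes. Each of 31 gene lists was described by the median difference of its measured members, given as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile below 2.5 or above 97.5 was taken as outside. Lists of fewer than 3 measured members got no median. The percentile describes these 2 libraries and ignores that genes of a list vary together. The groups, lists, thresholds, rule for named genes and most alternatives were chosen before the data were examined.

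Genes are named by a rule. It takes TFCP2L1, the 12 genes with a symbol that differ most in each direction, POU5F1, SOX2 and NANOG, and up to 4 members of each list with the largest absolute difference. The rule had ranked genes by the inner end of the counting interval, which the fallback replaced with the log2(FPKM + 1) difference. XIST and Y-linked genes were left out, and 1 gene the rule takes is not reported here. Gene symbols are those of the deposited table. Alternatives were 4 other scalings, other pseudocounts, minima and fold thresholds, a threshold on the counting interval, and other ways to set the list percentiles.

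Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures drawn in matplotlib 3.10.9. The steps were tested on simulated reads for 12999 genes at the depths of PB and PB-Tfcp2l1. Of 12799 genes simulated without a difference, 2 came out at least 2-fold apart. The size rule called 20% of 50 genes simulated at 2-fold, 93.6% of 47 at 3-fold, 100% of 52 at 4-fold and 100% of 51 at 8-fold, and the 95% interval held the simulated ratio for 95.4% of genes. These figures cover counting noise and no variation between cultures.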

Results

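The transcriptome of HES2 human embryonic stem cells carrying a Tfcp2l1 construct was compared with that of cells carrying the empty PB vector, to examine what overexpression of this transcription factor does to the maintenance of human embryonic stem cells. Each group held 1 library, so no difference below has a replicate check, and each describes these 2 libraries. Depth was nearly equal, at about 23120000 implied reads in the PB library and 23140000 in the PB-Tfcp2l1 library. Of 18256 genes in the table, 13208 reached 1 FPKM in at least 1 library. Their median FPKM was 8.71 in PB and 8.54 in PB-Tfcp2l1. The median difference in log2(FPKM + 1) was -0.065, so counts of genes below 0 start from a majority that is slightly lower.

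TFCP2L1 (gene ID 29842), the transcription factor carried by the construct, was at 2.84 FPKM in PB and 5.71 FPKM in PB-Tfcp2l1. The ratio was 2.01 (95% counting interval 1.82 to 2.22), on 607 and 1221 implied reads. On the log2(FPKM + 1) scale the difference was 0.81, just short of the 2-fold rule. The authors' deposited table gives TFCP2L1 a log2 ratio of 1.01 and an FDR of 1.1e-46 and calls it Up. That FDR covers counting error only. It is at most 0.001 for 5838 of 18256 genes and 3.0e-25 for SOX2 at a ratio of 1.15, so a small value does not mark a large difference. The construct is written in the style of a mouse gene, and reads from a mouse sequence would map to the human gene only in part, so the value checks the label only as far as those reads map.

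The transcription factors at the centre of the pluripotency network were close to equal in both libraries. POU5F1 was at 1015 FPKM in PB and 1066 FPKM in PB-Tfcp2l1, a ratio of 1.05 (1.034 to 1.066). SOX2 was at 177 and 205 FPKM, a ratio of 1.15 (1.12 to 1.19), and NANOG was at 87.0 and 88.0 FPKM, a ratio of 1.01 (0.968 to 1.06). None of the 16 measured members of the core pluripotency list differed 2-fold, and their median difference of -0.02 lay at percentile 64.9. UTF1, a chromatin-bound factor of undifferentiated cells, differed most in that list, at 118 FPKM in PB and 216 FPKM in PB-Tfcp2l1. PRDM14, a transcriptional regulator of pluripotent and germ cells, followed at 83.6 and 122 FPKM. DPPA2 was lower in PB-Tfcp2l1, at 11.5 against 15.1 FPKM.

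Genes associated with the naive and the primed state of pluripotency differed in both directions. KLF4 was 2.75-fold higher in PB-Tfcp2l1 (2.26 to 3.36), with 5.86 against 2.13 FPKM, and KLF5 was 2.32-fold higher (1.90 to 2.86), with 3.92 against 1.69 FPKM. Both are Krüppel-like factors of naive cells. DPPA3 and ALPPL2 of the same list were lower, at 3.11 against 5.08 FPKM and at 14.0 against 22.0 FPKM. The list of naive genes had 9 of 18 members measured, 1 of them at least 2-fold higher, and a median of 0.14 at percentile 94.6 (97.9, outside the range, with a minimum of 10 implied reads). OTX2, a homeobox factor of the primed state, was 2.94-fold higher in PB-Tfcp2l1 (2.61 to 3.32), at 22.7 against 7.73 FPKM. ZIC2 was 1.78-fold higher, while SALL1 was 1.84-fold lower. The 14 measured primed genes had a median of -0.01, at percentile 75.2, and OTX2 alone among them differed 2-fold.

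Across the transcriptome, 265 genes were at least 2-fold higher and 140 at least 2-fold lower in the PB-Tfcp2l1 library, together 3.07% of those measured. Of these, 34 were at least 4-fold higher and 7 at least 4-fold lower, and 88.6% of measured genes lay within 1.5-fold. SPP1 (gene ID 6696), which encodes the secreted phosphoprotein osteopontin, had the largest difference on the log2(FPKM + 1) scale among genes higher that have a symbol, although genes of lower expression had larger ratios. It was at 15.7 FPKM in PB and 166 FPKM in PB-Tfcp2l1, 10.6-fold higher (9.72 to 11.6). NPTX1 (gene ID 4884), a neuronal pentraxin, had the largest difference on the same scale among genes lower that have a symbol. It was at 33.8 FPKM in PB and 0.65 FPKM in PB-Tfcp2l1, 52.0-fold lower (41.6 to 65.4).

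**Figure D1:**
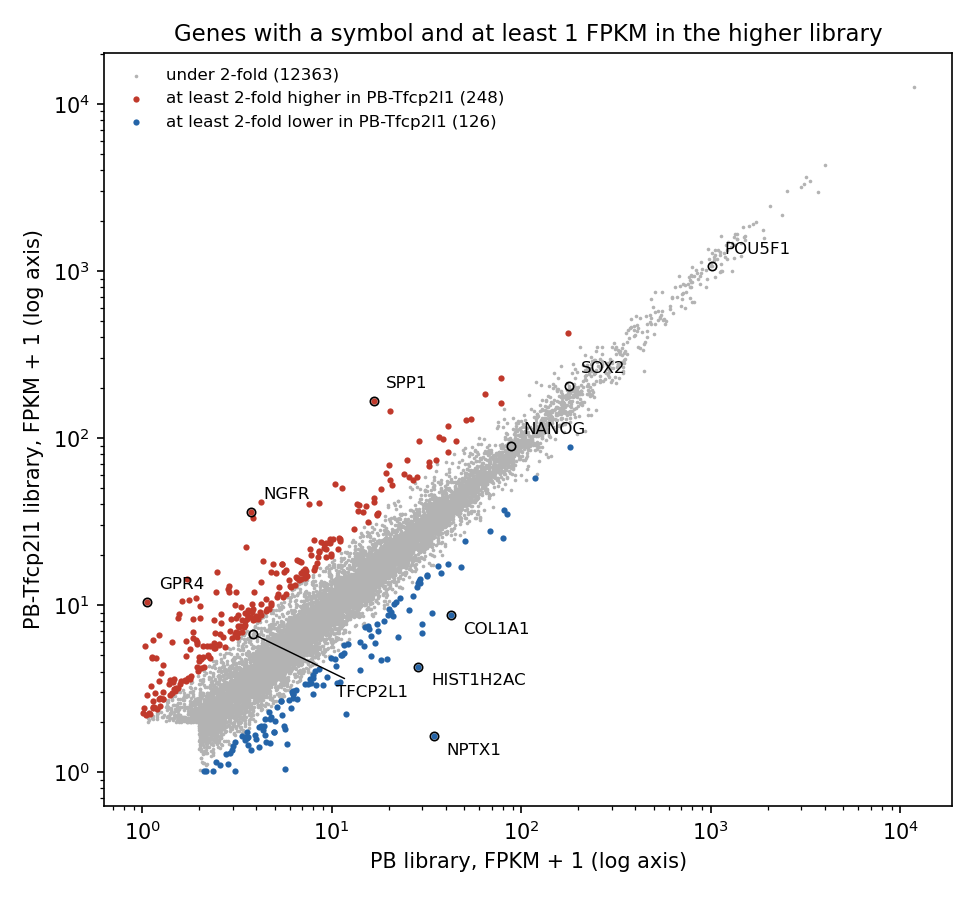
Expression of 12737 genes with a symbol and at least 1 FPKM in the higher library, with FPKM + 1 in PB on the horizontal and in PB-Tfcp2l1 on the vertical axis, both logarithmic, and 1 point per gene. Of these, 248 genes (red) were at least 2-fold higher and 126 (blue) at least 2-fold lower in PB-Tfcp2l1, and circles mark named genes, with POU5F1, SOX2 and NANOG on the diagonal.

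After SPP1, the genes higher by the most on the log2(FPKM + 1) scale were of varied function. GPR4, a proton-sensing receptor, was nearly absent from PB at 0.06 FPKM, on 4 implied reads, and reached 9.48 FPKM in PB-Tfcp2l1, a ratio of 158 (62.8 to 595). NGFR, the low-affinity neurotrophin receptor, was 12.8-fold higher (11.1 to 14.8), at 35.2 against 2.74 FPKM. FZD10, a receptor for WNT ligands, was 10.8-fold higher (8.48 to 14.1), and ADGRG1, an adhesion receptor, was 15.4-fold higher (11.6 to 20.4). The transcriptional repressors HES3 and SOX21 were 12.3-fold (9.11 to 16.8) and 11.3-fold (9.78 to 13.2) higher. WFDC2, a secreted protein, reached 143 FPKM against 19.2 FPKM. NEURL1, a ubiquitin ligase, was at 14.8 against 1.47 FPKM, and HPD, an enzyme of tyrosine breakdown, at 9.80 against 0.77 FPKM. PPP1R17, a phosphatase inhibitor, was at 21.3 against 2.51 FPKM. The antisense RNA JAKMIP2-AS1 was at 13.3 against 0.73 FPKM, and is uncertain because the use of strand is not known.

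In the other direction the largest differences on that scale after NPTX1 were in genes of varied function. SOX3, a transcription factor of neural progenitors, was 8.96-fold lower in PB-Tfcp2l1 (6.77 to 11.9), at 1.22 against 10.9 FPKM. COL1A1, the main chain of type I collagen, was 5.38-fold lower (5.03 to 5.75), at 7.73 against 41.6 FPKM. TAGLN, an actin-binding protein, was 4.93-fold lower (4.13 to 5.88), and MYL9, a myosin light chain, was 4.12-fold lower (3.55 to 4.82). SFRP1, a secreted inhibitor of WNT signalling, was at 3.79 against 18.5 FPKM. The neuropeptide gene NMU was at 6.70 against 28.99 FPKM, and IMPDH1, an enzyme of guanine nucleotide synthesis, at 3.70 against 17.2 FPKM. HIST1H2AC, a histone H2A gene, was at 3.29 against 27.7 FPKM, and FAM89B was at 0.47 against 4.83 FPKM. U2AF1L5 was at 0.04 against 4.67 FPKM, and is uncertain because it is a near-identical copy of U2AF1.

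The authors' deposited table calls 623 genes Up and 449 Down, exactly those with an absolute log2 ratio of at least 1 and an FDR of at most 0.001. Of the 265 genes higher here, 264 are called Up in the authors' deposited table, and of the 140 lower, 134 are called Down. This overlap is no separate check, as both rest on the same FPKM. A 2-fold difference in FPKM + 1 always means a larger FPKM ratio, so only the FDR cutoff could break it. Without a pseudocount, 508 measured genes were at least 2-fold higher and 423 at least 2-fold lower. The ratio and read minimum planned for counts, applied with implied reads, gave 538 higher and 398 lower. The number of genes thus depends on how low expression is treated.

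Among the 30 gene lists with at least 3 measured members, 12 had medians outside percentiles 2.5 to 97.5 of matched random lists, where 1.5 would be expected if lists were random draws. Histone genes stood lowest. All 10 were lower in the PB-Tfcp2l1 library, 5 of them at least 2-fold, and their median difference of -0.99 was below that of every random list (percentile 0). HIST1H2BK was at 14.1 against 31.0 FPKM, HIST2H2BE at 0.61 against 2.58 FPKM, and HIST1H2BJ at 0.42 against 3.12 FPKM, the last on 4 against 30 implied reads. Other members also rested on few reads, HIST2H2AA3 on 16 against 33 and HIST1H4C on 22 against 42. The counting intervals of HIST1H2BC (ratio 0.18 to 1.82, 6 against 10 reads) and HIST1H4H (0.56 to 1.35, 42 against 48 reads) included equal levels. Several histone genes have near-identical copies, so single values are uncertain, and whether RNA was selected by its poly(A) tail, which most histone RNA lacks, is not known. Cell cycle genes were also lower, 18 of 19 of them (17 under each of the 4 other scalings), by less than 2-fold each, with a median of -0.38 (percentile 0). MCM6 and MCM3, subunits of the replicative helicase, were 1.65-fold (1.57 to 1.72) and 1.39-fold (1.35 to 1.43) lower. CDK1, the mitotic kinase, was 1.53-fold lower (1.42 to 1.65), and BUB1, a spindle checkpoint kinase, was 1.44-fold lower (1.382 to 1.502).

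Targets of BMP signalling, of which 7 of 13 were measured, were lower in the PB-Tfcp2l1 library in 6 of 7 cases, with a median of -0.60 (percentile 0.03). ID3, an inhibitor of bHLH factors, was 2.30-fold lower (2.01 to 2.62), at 11.9 against 27.3 FPKM. ID4 was at 0.87 against 2.12 FPKM, ID2 at 3.62 against 6.42 FPKM, and the ligand gene BMP4, whose difference is the median, at 1.62 against 2.96 FPKM. ID1, the most highly expressed member, was only 1.14-fold lower (1.10 to 1.19), at 208 against 238 FPKM. Targets of WNT signalling had a median of 0.31 (percentile 99.8) but were split, with 6 of 10 higher. AXIN2, a feedback inhibitor of the pathway, was 1.88-fold higher (1.72 to 2.06) and MYC was 1.64-fold higher (1.55 to 1.74). APCDD1 was at 1.46 against 0.54 FPKM, while CCND1, which encodes cyclin D1, was 2.21-fold lower (2.06 to 2.36). The mean of the WNT list, 0.12, lay at percentile 88.3, inside the range.

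NODAL and activin targets had a median of 0.10 at percentile 95.8, inside the range, with 8 of 12 higher, whereas their mean of 0.30 lay outside it at percentile 99.7. LEFTY2, a secreted NODAL inhibitor, was 2.39-fold higher in PB-Tfcp2l1 (2.33 to 2.45), at 422 against 177 FPKM. NODAL itself was 1.83-fold higher (1.71 to 1.96), and PMEPA1 was 1.67-fold higher. FGF and ERK targets had a median of 0.09 at percentile 96.2, and a mean at percentile 97.9, just outside, with 10 of 17 higher and 7 lower. In that list FOS was at 14.8 against 4.60 FPKM, PHLDA1 at 15.0 against 6.08 FPKM and SPRY1 at 13.1 against 6.41 FPKM, while CCND1, which the list shares with the WNT targets, was 2.21-fold lower. Immediate early genes had a median of 0.01 (percentile 76.6) and a mean of 0.36 (percentile 99.4), with FOS, JUN and NR4A1 at least 2-fold higher among 10 measured. JUN was at 17.2 against 5.92 FPKM and NR4A1 at 18.4 against 8.37 FPKM.

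**Figure D2:**
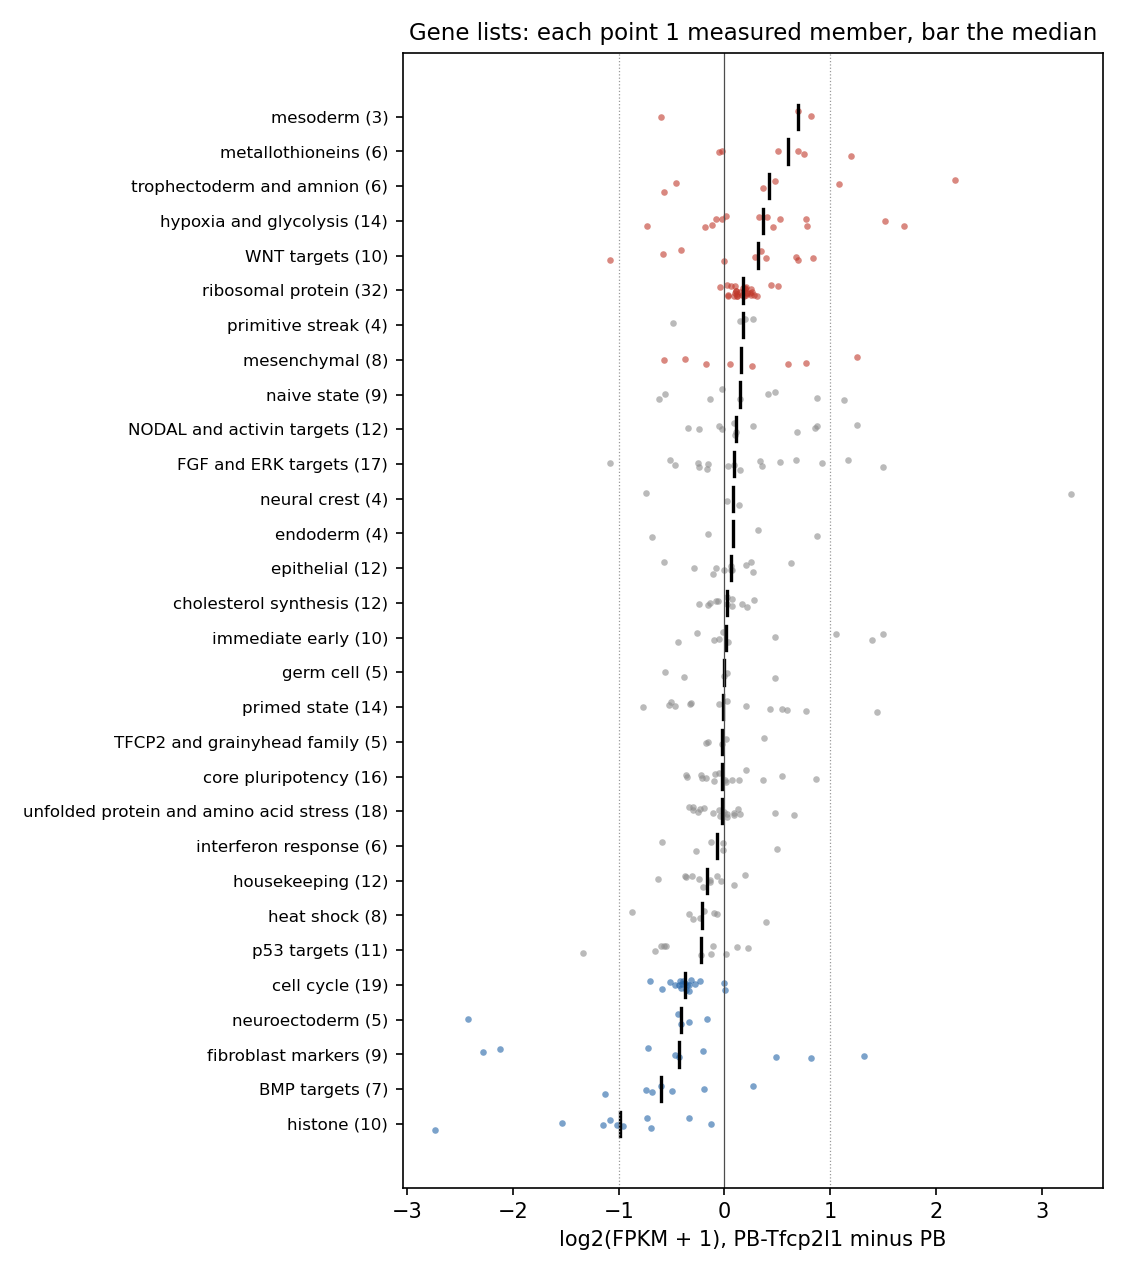
Differences in log2(FPKM + 1), PB-Tfcp2l1 minus PB, for the measured members of 30 gene lists, with 1 point per gene, a black bar at each median and the number of members in brackets. Lists whose medians lay above percentile 97.5 of random lists are red and those below 2.5 are blue; the histone list has the lowest median, -0.99, and the mesoderm list the highest, 0.69.

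Lineage markers were mostly low, and few members of each list were measured. Trophectoderm and amnion markers had 6 of 16 members measured and a median of 0.42 (percentile 99.4). KRT7, a keratin of simple epithelia, was 6.41-fold higher in PB-Tfcp2l1 (4.98 to 8.28), at 11.9 against 1.86 FPKM, and GATA2 was 3.76-fold higher (2.76 to 5.22), at 2.56 against 0.68 FPKM. TFAP2C was at 19.8 against 13.9 FPKM, while GABRP was at 0.37 against 1.04 FPKM. GATA2 reached 1 FPKM in PB-Tfcp2l1 alone and GABRP in PB alone. GATA3, under 1 FPKM in both libraries and so not measured, was lower, at 0.21 against 0.86 FPKM on 15 against 60 implied reads. That list's median lay at percentile 93.2 with a minimum of 10 implied reads and at 30.0, on the other side of the middle, with no minimum FPKM. Mesoderm markers had a median of 0.69 (percentile 99.3) over only 3 genes, with PDGFRA at 8.29 against 4.28 FPKM, KDR at 14.6 against 8.68 FPKM, and BMP4 lower as given above. It lay inside the range with no minimum (percentile 92.7), with a minimum of 10 reads (94.6) and by its mean (92.6). Neuroectoderm markers were lower in 5 of 5 measured cases, with a median of -0.41 (percentile 1.51), which lay inside the range with a minimum of 10 reads (4.81) or none (20.5). Besides SOX3, TUBB3, a neuronal tubulin, was at 129 against 172 FPKM, DCX at 1.33 against 2.16 FPKM and POU3F1 at 2.33 against 3.19 FPKM.

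The medians of the remaining lineage lists lay inside the range. Primitive streak markers had a median of 0.17 (percentile 88.2), with FGF8 at 5.94 against 4.75 FPKM, MIXL1 at 3.21 against 2.68 FPKM and TBX6 at 1.83 against 2.96 FPKM. Endoderm markers had a median of 0.08 (percentile 74.6; 98.6 with a minimum of 10 implied reads), with CER1, a secreted NODAL antagonist, at 5.27 against 2.43 FPKM and HHEX at 0.30 against 1.09 FPKM. Neural crest markers had a median of 0.08 (percentile 80.4) but, with NGFR far above the rest, a mean of 0.68 (percentile 99.2), and SOX10 was at 0.96 against 2.27 FPKM. Germ cell markers had a median of -0.0015 (percentile 64.9), with SOX15 at 12.2 against 16.2 FPKM. The TFCP2 and grainyhead relatives of TFCP2L1 had a median of -0.02 (percentile 58.2), with GRHL3 at 1.93 against 1.26 FPKM, GRHL2 at 4.43 against 5.15 FPKM, TFCP2 at 9.71 against 10.9 FPKM and UBP1 at 24.9 against 25.4 FPKM.

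Fibroblast markers had a median of -0.43 (percentile 0.09), but members went both ways. COL1A1 and TAGLN were at least 2-fold lower, whereas COL6A1, a chain of type VI collagen, was 2.53-fold higher in PB-Tfcp2l1 (2.44 to 2.61), at 127 against 50.3 FPKM. Mesenchymal genes had a median of 0.16 at percentile 97.6, which lay inside the range under 10 of 12 alternatives. VIM, the intermediate filament vimentin, was 2.41-fold higher (2.30 to 2.53), at 129 against 53.3 FPKM, MMP2 was 1.81-fold higher and FN1 was 1.53-fold higher. Epithelial genes had a median of 0.06 (percentile 92.9). CDH1, the gene of E-cadherin, was 1.55-fold higher (1.509 to 1.595), at 114 against 73.6 FPKM, while CLDN3 was at 9.52 against 14.7 FPKM.

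Genes of hypoxia and glycolysis had a median of 0.37, above that of every random list (percentile 100), with 9 of 14 higher and 5 lower in PB-Tfcp2l1. BNIP3, a mitochondrial protein of the hypoxic response, was 2.90-fold higher (2.73 to 3.08), at 117 against 40.2 FPKM. The peptide hormone gene ADM was 4.33-fold higher (3.34 to 5.63), and LDHA, the gene of lactate dehydrogenase A, was 1.71-fold higher (1.67 to 1.76), at 350 against 204 FPKM. NDRG1 was at 4.98 against 2.48 FPKM. The 5 lower members included EGLN3, 1.81-fold lower (1.56 to 2.11), at 4.44 against 8.05 FPKM. VEGFA, also among them, was 1.15-fold lower (1.06 to 1.25). SLC2A1, counted as higher, was nearly equal, at 65.88 against 65.42 FPKM, so the list did not move as one. Metallothioneins, which bind metal ions, had a median of 0.60 (percentile 99.99) over 6 genes, 4 of them higher. MT1X, the most highly expressed member, was nearly equal, at 37.8 against 38.4 FPKM, as was MT1E, at 2.89 against 3.04 FPKM. MT1H rested on only 36 against 18 implied reads. MT1F was 2.41-fold higher (1.88 to 3.13) and MT1G 1.67-fold higher (1.303 to 2.172). Ribosomal protein genes had a median of 0.18 (percentile 100), with 31 of 32 higher (31 or 32 under the other scalings), none of them by 2-fold. RPL13A was at 1613 against 1133 FPKM and RPS3 at 925 against 681 FPKM.

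The medians of other stress and maintenance lists lay inside the range. Targets of p53 had a median of -0.22 (percentile 5.80), but lay outside by their mean (0.53) and with genes of at least 1000 bases alone (0.32), with BTG2, an antiproliferative gene, 3.62-fold lower (2.83 to 4.62) and CDKN1A, a cyclin-dependent kinase inhibitor, 1.57-fold lower (1.35 to 1.83). Heat shock genes had a median of -0.21 (percentile 6.04), with HSPA1B at 32.1 against 59.6 FPKM. Interferon response genes had a median of -0.07 (percentile 46.3), with IFITM1 at 681 against 481 FPKM and ISG15 at 13.1 against 20.3 FPKM. Genes of the unfolded protein and amino acid response had a median of -0.03 (percentile 67.6), with SLC7A11, a cystine transporter, at 3.84 against 2.07 FPKM. Cholesterol synthesis genes had a median of 0.02 (percentile 87.7), with HMGCS1 at 46.4 against 38.0 FPKM. Housekeeping genes had a median of -0.17 (percentile 8.55), with ACTB at 2958 against 3669 FPKM and B2M at 45.0 against 70.1 FPKM. Mitochondrially encoded genes had 0 of 12 members in the table and are not analysed here.

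The medians of the core pluripotency, primed, and TFCP2 and grainyhead lists were slightly below 0 while their means, 0.04, 0.07 and 0.01, were above it. These medians and those of the germ cell and the unfolded protein and amino acid lists turned positive under at least 3 of the 4 other scalings, so no direction is given for them.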

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

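The alternative with genes of at least 1000 bases was chosen after seeing the data. A ratio of at least 2 on at least 50 reads was the rule planned for counts. Its use with implied reads was chosen after seeing the data. The number of genes higher (265) and lower (140) in the PB-Tfcp2l1 library moved with the treatment of low expression. The authors' deposited log2 ratio without a pseudocount gave 508 and 423 measured genes, a pseudocount of 0.1 FPKM gave 476 and 369, and a ratio of 2 on 50 reads gave 538 and 398. A threshold of 1.5-fold gave 766 and 743, and one of 4-fold gave 34 and 7, by construction. A minimum of 200 reads, which can only remove genes from these counts, left 88 genes lower. Adding 1 CPM to both libraries, at the median length a smaller pseudocount than 1 FPKM, gave 213 lower. The 4 other scalings gave 270 to 312 higher and 119 to 138 lower. For TFCP2L1 the difference of 0.81 became 1.01 without a pseudocount, 0.98 with 0.1 FPKM and 0.98 with 1 CPM, since a smaller pseudocount shrinks a low gene less. The number of gene lists outside the range stayed between 8 and 14 around the 12 reported. Of those 12, 7 kept their side under every alternative run: BMP targets, cell cycle, fibroblast markers, hypoxia and glycolysis, metallothioneins, ribosomal proteins and histones. Histones and metallothioneins had too few genes of at least 1000 bases, so 11 rather than 12 alternatives were run on them. The 4 other scalings shift a list and its random lists nearly alike, so they could move a percentile only slightly. With no minimum the trophectoderm and amnion list turned from percentile 99.4 to 30.0, as genes near 0 FPKM entered it, and the neuroectoderm list went to 20.5. All 44 named genes at least 2-fold apart kept their direction under the 7 alternatives run on them, but these could not have reversed it. A pseudocount leaves the sign of a difference unchanged, and no scaling factor exceeded 0.073 in absolute log2. No paired analysis was possible because each group held 1 library. At the median length 1 FPKM is about 69.3 reads, but short genes rest on fewer, such as HIST1H2BJ, whose 3.12 FPKM in PB are 30 reads. The intervals cover that counting error, whereas variation between cultures cannot be estimated without a second culture per group.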

Other observations

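The tests and gene groups in this part were all chosen after the values were seen. Gene ontology terms carried by the authors' deposited table were scanned as a wider set of groups, 1609 terms with 10 to 200 measured genes. Of these, 7 had medians below percentile 0.05 of matched random lists and 10 above 99.95, where 0.805 would be expected at each end. Genes lower in the PB-Tfcp2l1 library belonged to nucleosome organization (48 genes, median -0.36, 44 lower), DNA-dependent DNA replication (49 genes, median -0.27, 42 lower), S phase (103 genes, median -0.18, 89 lower), mitotic M phase (129 genes, median -0.17, 96 lower) and condensed nuclear chromosome (25 genes, median -0.30, 19 lower). Genes of cell-substrate adherens junctions (55 of 83 lower, median -0.19) and of receptor activity (44 of 62 lower, median -0.22) were lower too. The 10 terms on the other side were of mixed kinds. They were basement membrane (15 genes, median 0.42, 10 higher), positive regulation of epithelial cell proliferation (11 genes, median 0.35, 10 higher), serine-type endopeptidase activity (21 genes, median 0.25, 13 higher), hair follicle development (18 genes, median 0.23, 13 higher) and epidermis development (37 genes, median 0.19, 25 higher). The others were respiratory tube development (35 genes, median 0.15, 24 higher), viral gene expression (75 genes, median 0.15, 66 higher), pancreas development (94 genes, median 0.13, 71 higher), behavior (52 genes, median 0.12, 28 higher) and cell adhesion (114 genes, median 0.07, 61 higher). Counts of genes higher and lower are on the reported scaling, and terms share genes, so these are not separate findings. The median difference of all measured genes with a symbol was -0.067, so most genes count as lower on that scaling. The percentiles take this into account, whereas the counts do not.

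Replacement histone genes, which are expressed outside S phase, were lower in the PB-Tfcp2l1 library in 10 of 10 measured cases, at percentile 0.05 of random lists. H1F0, a linker histone, was at 34.3 against 83.1 FPKM, H1FX at 75.9 against 137 FPKM, H2AFY at 18.8 against 37.1 FPKM and H2AFY2 at 9.51 against 19.1 FPKM. H3F3B differed less, at 108 against 118 FPKM. Gene IDs were placed on chromosomes with the GRCh38.p14 gene table, which held 99.8% of 17579 IDs. The median difference of the 22 autosomes ran from -0.10 to -0.0037, whereas 1 extra copy of a chromosome in every cell of one culture would shift expression proportional to copy number by 0.58.

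The joint lower level of histone and cell cycle genes was set against 3 technical explanations. Gene length bias would need random lists matched on length and expression to be as low, but both the histone and the cell cycle list lay at percentile 0 of such lists. Matching on length had little room to change this. The shortest of 10 length groups had a median difference of -0.10 and the longest one of -0.02, so length went with small differences only. Scaling of the libraries would need a factor large enough to bring the cell cycle median of -0.38 to 0. The 4 other scalings had factors of at most 0.073 in absolute log2, so they could not do this. The highest median under them was -0.30. They show that a scaling error of their size is too small, and a larger error was not tested. Uneven capture of RNA without a poly(A) tail cannot account for polyadenylated cell cycle genes, and replacement histones, also polyadenylated, had a median of -0.39. Since that is nearer 0 than the -0.99 of the histone list, part of the histone difference may still come from capture, and a difference due to the construct or between single cultures stays open and was not tested.

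The lower COL1A1, TAGLN and MYL9 in the PB-Tfcp2l1 library could come from fibroblasts in the PB culture, which would bring other abundant fibroblast transcripts with them. In the PB library COL3A1 was at 0.05 FPKM and POSTN at 0.27 FPKM, the latter 0.65% of the 41.6 FPKM of COL1A1, which argues against this. COL6A1 and VIM, also abundant in fibroblasts, were higher in PB-Tfcp2l1. Other genes that fibroblasts express were lower there, COL1A2 at 15.0 against 25.4 FPKM, THY1 at 133 against 192 FPKM, COL6A2 at 46.6 against 53.8 FPKM, COL5A2 at 2.42 against 9.69 FPKM, CNN1 at 8.49 against 13.0 FPKM, ACTA2 at 1.02 against 1.72 FPKM and ACTG2 at 0.81 against 4.68 FPKM. A difference in the stem cells themselves, in another differentiated cell type, or between single cultures stays open and untested.

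TFCP2L1 itself was only 2.01-fold higher, and a construct with the coding sequence alone is a candidate explanation for part of that small size. The deposited FPKM divides by 9306 bases, of which 1437 are coding in GENCODE v29, so reads confined to the coding part would be diluted. If all added reads lay there, coding sequence would be 7.54-fold more abundant in PB-Tfcp2l1. The table holds 1 value per gene, so this cannot be told apart from even coverage, nor from loss of mouse reads in alignment.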
